A study of Mus musculus with 4 samples.

How the data were processed

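Crypt cells of the small intestine from adult mice were measured by 10x Genomics droplet RNA sequencing with unique molecular identifiers (UMIs), in 2 libraries labelled WT and 2 labelled Hmgcs2-KO. The labels give the strain as C57BL/6 for all 4 libraries and say that crypts were dissociated and the cells sorted by flow cytometry, with no gate named. The labels do not say whether the 2 libraries of a genotype came from separate animals. The p-values of the genotype tests on genes and shares therefore measure only the spread between these libraries. Those of camera at the preset correlation, of gene pairs and of chromosome 3 rest on genes, which are not independent replicates. Those for Hmgcs2 between classes rest on class sums from the 2 WT libraries.

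The deposited values are raw UMI counts per gene and cell barcode, 1 table per library, with no normalization by the authors. Per the submitters' processing notes the reads went through Cell Ranger 1.3.1 with the mm10 build. Barcodes had already been filtered to cells, since the lowest total per barcode was between 1913 and 2755 UMIs. The steps for cell calling and doublets are not stated. All 33217 gene identifiers were the same in the 4 tables, 32064 matched GENCODE mouse release M21 for positions on GRCm38, and 347 shared a symbol with another identifier. For each shared symbol the identifier with the most UMIs kept the bare symbol, and the others carry the identifier in their name.

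The deposited counts held 31348229 UMIs in 4676 barcodes for WT replicate 1 and 36670189 UMIs in 5485 barcodes for WT replicate 2. They held 28196685 UMIs in 3794 barcodes for Hmgcs2-KO replicate 1 and 31373962 UMIs in 4649 barcodes for Hmgcs2-KO replicate 2. Cells were kept with at least 500 genes with a UMI and at most 25% of UMIs from mitochondrial genes, which removed 150 and 560 barcodes. Doublets were sought per library with the Scrublet method of scanpy 1.11.5, at an expected rate of 4%. Its automatic threshold marked 44 cells, 0.246% of those tested, which is far below the expected rate, so doublet removal was in effect not achieved. An alternative that removed the 4% of cells with the highest doublet scores was chosen after seeing the data. The 17865 kept cells were 4376, 5298, 3692 and 4499 in WT replicates 1 and 2 and Hmgcs2-KO replicates 1 and 2. Free RNA in the droplets was not subtracted, because empty droplets were not analysed here.

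Cells of all libraries were clustered together from counts per 10000 on the log scale, with 2000 variable genes chosen within library, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 (leidenalg 0.10.2, scikit-learn 1.9.0, numpy 2.4.6, Python 3.11.15). This gave 30 clusters. A cluster took the name of a class when at least 3 of that class's fixed marker genes were among its 50 leading genes, the class with the most such markers was taken, and no other class had more markers among the 10 leading genes. Leading genes were detected in at least 25% of the cluster's cells and ranked by their fold over the mean of the other clusters. The markers were fixed before the data were examined, whereas the numbers in this naming rule were set after the clusters were seen. Clusters 3, 5, 8, 11 and 14 met no class's rule and stayed unnamed.

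UMIs were summed over the cells of a library, for all kept cells and for each class with at least 20 cells in every library, so that the library and not the cell was the replicate. Genotypes were compared with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3, with TMM scaling, filterByExpr by genotype and Benjamini-Hochberg adjustment at 0.05. Positive log2 values mean higher in Hmgcs2-KO. CPM are the library-scaled counts of edgeR's cpm function with TMM factors, except for Xist and the immune, stromal and red blood cell markers, where no TMM factor was applied. Hmgcs2 was compared between classes of the WT libraries with library as a block, and the difference in genotype effect between stem-like and enterocyte-like cells was tested as an interaction with library as a block. Shares of cells carry exact Clopper-Pearson intervals at 95%, and single levels of Hmgcs2 carry exact Poisson intervals at 95%, both for counting error only. The floor of a level is 3 UMIs per library. Shares were compared by an exact two-sided permutation test, which cannot go below a p of 0.333 with 2 libraries against 2, and by the edgeR test on cell counts over 8 classes, unnamed cells included.

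Gene lists for metabolism, cell types, signalling, cell cycle, immune response and dissociation were fixed before the data were examined, as were the comparisons, the alternatives and the rule for naming genes. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry beside it, adjusted over the lists of a comparison. Medians of lists are of edgeR log2 values, but under alternatives they are of limma-voom log2 values, given there beside the limma-voom median of all libraries. The naming rule takes Hmgcs2 first. It then takes genes with adjusted p under 0.05, a mean of at least 10 CPM and both libraries of 1 genotype above both of the other. Of these it names the 12 largest increases and the 12 largest decreases in all cells and in stem-like cells, and the 5 and 5 largest elsewhere. Where fewer than 5 pass, the 5 genes with the smallest p are named as having missed the threshold. Predicted genes, Rik genes and ribosomal and mitochondrial genes are counted but not named by this part. For lists it names up to 4 members past the threshold, or the 2 most abundant members where fewer than 2 pass.

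Alternatives covered RLE scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a replicate block, each library left out in turn, 1000 genes per cell, no cell filter, doublets kept, cells thinned to 3000 UMIs with 1728 shallower cells left out, 10260 cells in the same number per class in every library, Leiden resolutions 0.5 and 2.0, and components centred per library. When 1 library is left out, the lone library of its genotype is assumed to vary like the others.

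The steps were tested on simulated data made from the libraries' own counts. At a 2-fold change edgeR recovered 18.4% of changed genes in all cells and 68% in stem-like cells, and at 4-fold 82% and 94%. Unchanged genes made up 16 of 117 calls in all cells and 12 of 168 in stem-like cells, which is more than 5% of the calls. In both, a simulated list changed 1.5-fold had an unadjusted p under 0.05 with either correlation of camera. With the estimated correlation these p were 0.0111 and 0.00653. The real lists were adjusted over 27 lists in all cells and 25 in stem-like cells, which the simulated list was not. It was thus not shown that the estimated correlation could pass a changed list after that adjustment. Simulated genes were drawn independently, whereas the stem cell signature had an estimated correlation of 0.915 in all cells. The simulation therefore cannot show how either form behaves on correlated lists. Positions and distances used scipy 1.17.1 and 10000 random gene sets. Sex-linked transcripts were read only as a check of the libraries. Stromal, red blood cell and sex-linked lists had too few measured genes for a list test in all cells.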

Results

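The data are UMI counts of small intestinal crypt cells from mice with the Hmgcs2 gene (WT, 2 libraries) and mice labelled as lacking it (Hmgcs2-KO, 2 libraries). Hmgcs2 encodes mitochondrial HMG-CoA synthase, the enzyme that commits acetyl units to ketone body synthesis. The median cell held 6381 UMIs in WT replicate 1, 6328 in WT replicate 2, 6411 in Hmgcs2-KO replicate 1 and 5797 in Hmgcs2-KO replicate 2. Median genes per cell were 1979, 1941, 1886 and 1753 in the same order. Each library held more barcodes than the average recovery stated in the labels. Immune marker transcripts were rare, at 8.68 to 12.6 CPM, and stromal and red blood cell markers stood at 3.17 to 7.46. Xist was measured at 1158, 611, 1031 and 839 CPM, and Y-linked genes at 2, 1, 0 and 0 UMIs.

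The first comparison asked which cell classes made up each genotype's libraries. Paneth-like cells, which carry lysozyme and alpha-defensins, made up 2.77% ± 1.13 (SD, n = 2) of WT cells and 13.6% ± 0.290 (SD, n = 2) of Hmgcs2-KO cells, a 4.92-fold difference. Proliferating-like cells were also more frequent in each Hmgcs2-KO library, at 22.5% and 17.9% against 14.6% and 9.85%. Enteroendocrine-like cells, which make gut hormones, were less frequent in each Hmgcs2-KO library, at 0.786% and 0.60% against 1.85% and 1.0%. Stem-like cells (15.7% and 6.34% in WT, 16.3% and 13.2% in Hmgcs2-KO), enterocyte-like cells (14.1% and 36.3%, 12.5% and 21.9%), goblet-like cells (22.5% and 14.2%, 18.1% and 13%) and tuft-like cells (4.02% and 1.11%, 2.79% and 1.87%) overlapped between the genotypes. Unnamed clusters held 25.3% and 27.7% of WT cells and 13.3% and 18.1% of Hmgcs2-KO cells.

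**Figure D1:**
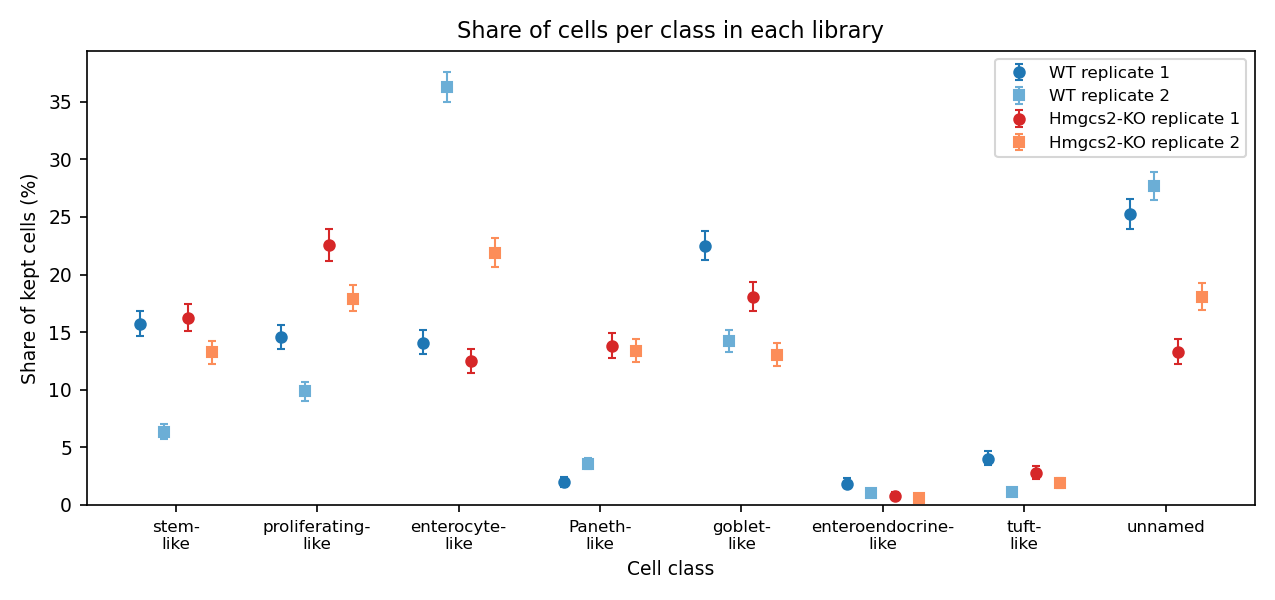
Share of kept cells (%) in each cell class, with 1 point per library (blue, WT; red and orange, Hmgcs2-KO) and exact 95% binomial intervals. Paneth-like cells lie at 13.8% and 13.4% in the Hmgcs2-KO libraries and at 1.97% and 3.57% in the WT libraries.

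The edgeR test on cell counts passed its threshold for Paneth-like cells alone among the 8 classes, with a log2 fold change of 2.30 ± 0.60 (SE) and an adjusted p of 0.0122. For proliferating-like cells it gave 0.73 ± 0.57 with an adjusted p of 0.445, and for enteroendocrine-like cells -1.04 ± 0.62 with 0.445. The remaining values were 0.42 ± 0.57 (adjusted p 0.632) for stem-like, -0.55 ± 0.57 (0.557) for enterocyte-like, -0.24 ± 0.57 (0.778) for goblet-like and -0.14 ± 0.59 (0.815) for tuft-like cells. The exact permutation test gave 0.333 for Paneth-like cells, the smallest p it allows with n = 2 per genotype. Cells were also counted by 19 of the 24 Paneth products, those at least 10 times as abundant in WT Paneth-like cells as in any other class, a choice that rests on the clusters. From these genes 81 and 194 WT cells and 515 and 610 Hmgcs2-KO cells took over 10% of their UMIs, which was 1.85%, 3.66%, 13.9% and 13.6% of the libraries. WT replicate 2 stood apart in its enterocyte-like share. Without it the enterocyte-like log2 ratio was 0.28 and the stem-like ratio -0.09. Without WT replicate 1 the stem-like ratio was 1.22, the tuft-like ratio 1.06, the goblet-like ratio 0.13 and the enteroendocrine-like ratio -0.53. Without Hmgcs2-KO replicate 2 the tuft-like ratio was 0.12. The Paneth-like log2 ratio was 1.93 without WT replicate 1 and 2.79 without WT replicate 2.

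The next comparison asked which cells carry Hmgcs2 and whether the transcript follows the labels. In WT libraries Hmgcs2 (ENSMUSG00000027875, chromosome 3, 98280435 to 98310738) was highest in stem-like cells, at 43.2 and 65.1 CPM, which was 3.0 ± 0.25 (SE) log2 units above the mean of the other classes (adjusted p 7.55e-14). Proliferating-like cells were 1.52 ± 0.27 above that mean (adjusted p 9.51e-06) and enterocyte-like cells 2.27 log2 units lower, with a value of -2.27 ± 0.47 (adjusted p 4.44e-05). Paneth-like (adjusted p 0.880), goblet-like (0.254), enteroendocrine-like (0.418) and tuft-like cells (0.874) did not pass.

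Hmgcs2 transcript was present in both Hmgcs2-KO libraries. Stem-like cells held 11.7 CPM (exact Poisson interval 8.42 to 15.9) in Hmgcs2-KO replicate 1 and 36.2 CPM (29.9 to 43.5) in the library labelled Hmgcs2-KO replicate 2, against 43.2 (36.9 to 50.2) and 65.1 (54.2 to 77.6) in WT. The log2 fold change of -1.15 ± 0.35 had an adjusted p of 0.372. A fit that leaves 1 Hmgcs2-KO library holds none of the spread between these libraries, whose intervals did not overlap. Without the library labelled Hmgcs2-KO replicate 2 the log2 fold change was -2.17, and without Hmgcs2-KO replicate 1 it was -0.54. With no filter on low counts it was -1.14 with 2.56e-07. Over all cells the levels were 11.4 and 9.27 CPM in WT and 3.79 and 12.8 CPM in Hmgcs2-KO, with a log2 fold change of -0.31 ± 0.57 and an adjusted p of 0.856, which turned to 0.32 without Hmgcs2-KO replicate 1. Proliferating-like cells held 22.6 and 23.7 CPM in WT and 4.02 and 22.7 CPM in Hmgcs2-KO (log2 -0.83 ± 0.53, adjusted p 0.999). The value was -2.52 without the library labelled Hmgcs2-KO replicate 2, -0.80 without WT replicate 2 and -0.02 without Hmgcs2-KO replicate 1. It passed with no filter on low counts (-0.82, adjusted p 0.00428). Goblet-like cells held 4.76 and 6.06 CPM against 0.758 and 3.15 (-1.52 ± 0.55, adjusted p 0.931), which was -0.76 without Hmgcs2-KO replicate 1 and -2.79 without the library labelled Hmgcs2-KO replicate 2. Paneth-like cells held 1.01 and 2.04 CPM in WT and 2.22 and 5.19 CPM in Hmgcs2-KO (1.10 ± 0.67, adjusted p 0.608), but the value of WT replicate 1 rests on 1 UMI, where 3 UMIs would be 3.02 CPM, so a direction was not detectable at this depth. Enterocyte-like cells held 3.82 and 0.417 CPM in WT and 0.619 and 2.06 CPM in Hmgcs2-KO (-0.19 ± 1.07, adjusted p 0.998). The direction there turned without WT replicate 1 and without Hmgcs2-KO replicate 1. In the enteroendocrine-like cells of the Hmgcs2-KO libraries there were 0 UMIs, where 3 UMIs would be 19.5 and 27.9 CPM and the exact Poisson upper limits were 24.0 and 34.4 CPM. The labels do not say which part of the gene was deleted nor where the tags lie, so remaining tags alone do not contradict a label. Tag position would not set libraries of 1 genotype apart, yet the Hmgcs2-KO libraries differed beyond counting error in proliferating-like cells. Exact Poisson intervals there were 2.63 to 5.90 CPM in Hmgcs2-KO replicate 1 and 18.9 to 27.0 CPM in the library labelled Hmgcs2-KO replicate 2. Whether the label of the library labelled Hmgcs2-KO replicate 2, with its Hmgcs2 level within the WT range in proliferating-like cells, is right was not tested, and every Hmgcs2-KO value rests on that label. In its share of Paneth-like cells, 13.4%, it lay with Hmgcs2-KO replicate 1 at 13.8% and apart from WT at 1.97% and 3.57%. In Mptx1 over all cells it also lay with that library, at 12.3 and 20.1 CPM against 209 and 279 CPM in WT. Both the Paneth-like share and Mptx1 were picked for their difference between the genotypes, so neither tests the label.

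**Figure D2:**
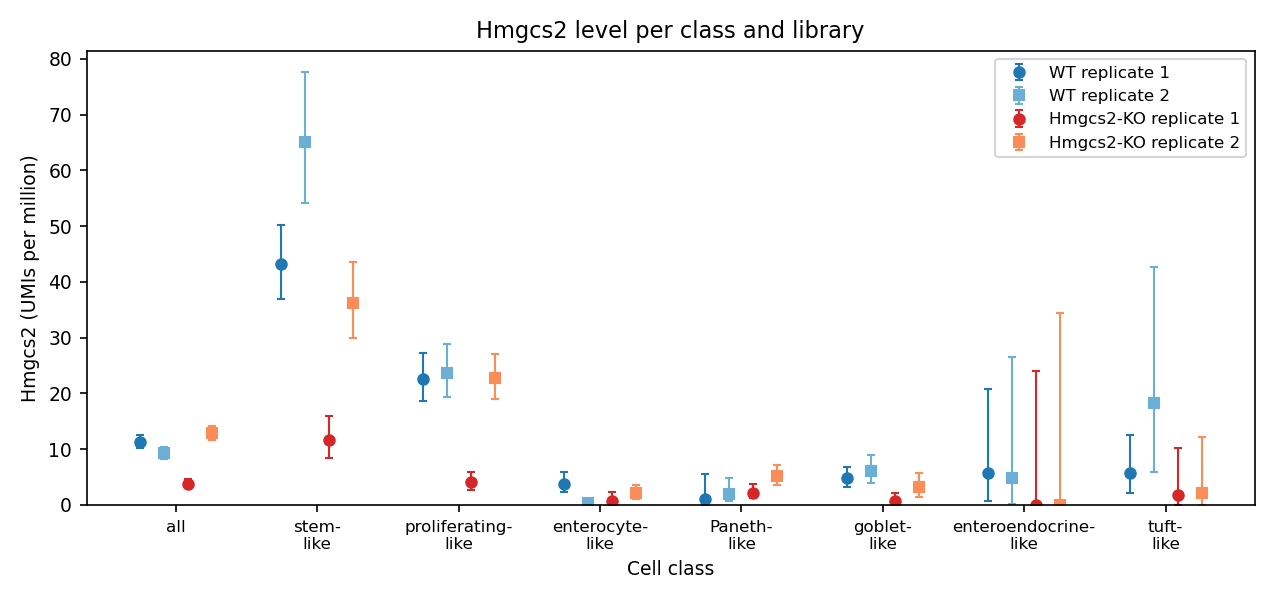
Hmgcs2 level (CPM) per cell class, with 1 point per library (blue, WT; red and orange, Hmgcs2-KO) and exact 95% Poisson intervals. In stem-like cells Hmgcs2-KO replicate 1 lies at 11.7 and the library labelled Hmgcs2-KO replicate 2 at 36.2, against 43.2 and 65.1 in WT.

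Over all cells, the genotypes were compared to see what differs in the crypt as a whole. Of 12941 genes tested by edgeR, 2 rose and 0 fell, while 924 had an unadjusted p under 0.05 against 647 by chance. The 2 are processed pseudogenes outside the naming rule and were named after their values were seen. Gm10036 rose from 0.720 to 50.1 CPM (log2 6.11 ± 0.27, adjusted p 0.0319) and Gm5900 from 0.217 to 17.5 CPM (log2 6.31 ± 0.25, adjusted p 0.0319). DESeq2 called 117 genes and limma-voom 0. Named genes that missed the threshold were Ang4, a microbicidal ribonuclease (505 CPM in WT, 2780 in Hmgcs2-KO, log2 2.46 ± 0.17, adjusted p 0.0821), the mucosal pentraxin Mptx2 (243 and 3497 CPM, 3.85 ± 0.29, 0.104), the alpha-defensin Defa3 (30.0 and 162 CPM, 2.44 ± 0.19, 0.114), Mptx1 (244 and 16.2 CPM, -3.91 ± 0.32, 0.118) and the lipase Pnliprp2 (19.6 and 162 CPM, 3.04 ± 0.26, 0.121). Each was separated between the genotypes in all 4 libraries, as were 42.1% of all genes, where chance gives 33.3%. Calls numbered 1837 without WT replicate 1, 193 without WT replicate 2 and 7 without the library labelled Hmgcs2-KO replicate 2.

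Of 27 gene lists, 12 moved over all cells by camera at the preset correlation, and 0 by camera with an estimated correlation and 0 by fry. Paneth cell products rose together: all 24 were positive, 0 passed over all genes and 21 passed adjusted over the list alone, with a median log2 of 1.97 (adjusted p 1.33e-29). Defa24 went from 13639 to 86242 CPM and Gm15284 from 5212 to 39767 CPM. G2 and M phase genes, such as Cks2 (133 and 191 CPM) and Tubb4b (320 and 332 CPM), had a median of 0.59 with all 30 positive, 0 over all genes and 15 adjusted over the list alone (adjusted p 3.21e-19). Enteroendocrine cell products fell with a median of -1.19 (adjusted p 2.58e-06), where 0 passed over all genes and, adjusted over the list alone, 4 were lower (Gcg, Chgb, Pyy and Nts) and 1 higher (Ghrl). The cholesterol synthesis list had a median of -0.16 (adjusted p 0.00314), with 0 members passing on either count; Fdps stood at 110 and 107 CPM and Hmgcs1 at 106 and 87.8. For these 4 lists the adjusted p = 0.760 with an estimated correlation.

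The other 8 lists had 0 members passing, over all genes or adjusted over the list alone. They rose for S phase (median 0.51, adjusted p 1.15e-14; Slbp, Gmnn), interferon response (0.88, 2.36e-08; Isg15 at 61.4 and 156 CPM, Psmb8 at 217 and 202), the stem cell signature (0.41, 3.57e-05; Slc12a2, Sox9) and Wnt targets (0.44, 3.35e-05; Mmp7, Ccnd2). They fell for absorptive enterocyte products (-0.73, 9.98e-05; Apoa1 at 4531 and 2478 CPM, Rbp2), fatty acid oxidation and PPAR targets (-0.23, 0.00314; Fabp2, Fabp1), nuclear oxidative phosphorylation (-0.18, 0.00244; Cox4i1, Cox8a) and the citrate cycle (-0.12, 0.0383; Mdh2, Sdhb). For these 8 lists the adjusted p = 0.875 with an estimated correlation. Enzymes of ketone body synthesis and use did not pass (median -0.01, adjusted p 0.895; Oxct1 at 101 and 93.7 CPM, Acat1 at 88.5 and 104). Neither did fatty acid synthesis (0.13, 0.628), glycolysis (-0.22, 0.0795), the mitochondrial genome (-0.17, 0.111), the Notch pathway (-0.06, 0.628), secretory progenitors (-0.05, 0.443), goblet cell products (-0.15, 0.127), MHC class II (-0.28, 0.752), endoplasmic reticulum stress (-0.09, 0.741), histone deacetylases (0.11, 0.458), p53 and apoptosis (-0.22, 0.516) or immune cell markers (-0.20, 0.826). The mean was positive where the median was negative for immune cell markers (0.16), endoplasmic reticulum stress (0.01) and the ketone body list (0.06), and for immune cell markers camera pointed up. The medians of tuft cell products (-0.14, 0.681), antimicrobial and Reg genes (-0.37, 0.752) and dissociation genes (-0.17, 0.954) were negative while camera's direction was up.

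With class shares made equal, the all-cells medians of the called lists shrank or turned sign, except that of interferon response. Medians in this paragraph are of limma-voom log2 values. With the same number of cells per class in every library, the median of Paneth cell products went from 2.06 to 0.04 (adjusted p 0.800), of the stem cell signature from 0.50 to 0.01 (0.800) and of fatty acid oxidation from -0.23 to -0.05 (0.632). Interferon response (1.38 to 1.53, 1.71e-23), G2 and M phase (0.60 to 0.14, 2.48e-05), S phase (0.54 to 0.10, 0.0242) and absorptive enterocyte products (-0.65 to -0.20, 2.14e-07) passed at the preset correlation. In all cells these 4 lists had an adjusted p = 0.760 with an estimated correlation for G2 and M phase and an adjusted p = 0.875 with an estimated correlation for the other 3. Wnt targets (-0.01), cholesterol synthesis (0.09), oxidative phosphorylation (0.01) and enteroendocrine cell products (0.32, adjusted p 0.00516) turned sign, and the citrate cycle stood at 7.88e-05. Leaving out WT replicate 2 turned the medians of fatty acid oxidation (5.83e-04), the citrate cycle (0.02), oxidative phosphorylation (0.01) and absorptive enterocyte products (0.05), and ended the calls of the stem cell signature (adjusted p 0.878) and Wnt targets (0.0972). Leaving out Hmgcs2-KO replicate 1 turned fatty acid oxidation (0.02) and ended the citrate cycle (0.416), oxidative phosphorylation (0.373) and enterocyte (0.112) calls. The cholesterol call ended without WT replicate 1 (0.0759) and without the library labelled Hmgcs2-KO replicate 2 (0.268), and its median went from -0.14 to -0.21 without Hmgcs2-KO replicate 1.

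Interferon response depended on the WT library, with a limma-voom median of 1.38 over all cells that was 0.39 (adjusted p 0.0405) without WT replicate 1, 2.34 without WT replicate 2 and 0.92 without Hmgcs2-KO replicate 1. Without WT replicate 1 the medians were -0.60 (adjusted p 0.00384) for enteroendocrine cell products against -0.96 with all libraries, 1.04 for the stem cell signature against 0.50, and 0.88 for Wnt targets against 0.45. They were -1.30 for absorptive enterocyte products against -0.65, -0.45 for fatty acid oxidation against -0.23, -0.34 for oxidative phosphorylation against -0.17 and -0.28 for the citrate cycle against -0.11. Without the library labelled Hmgcs2-KO replicate 2 absorptive enterocyte products stood at -1.12, fatty acid oxidation at -0.49, oxidative phosphorylation at -0.28 and the citrate cycle at -0.20.

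The central comparison asked what differed between libraries labelled Hmgcs2-KO and WT in stem-like cells, the class in which the WT level of Hmgcs2 was highest. Several interferon-induced genes and alpha-defensins rose, and a small group that includes Gdpd3, Cfi, Fgf1, Lamtor3 and S100g fell by large factors. As lists, interferon response had an adjusted p = 0.637 with an estimated correlation and Paneth cell products an adjusted p = 0.622 with an estimated correlation. Alpha-defensins are Paneth cell products, whose free RNA was not subtracted. Ifi27l2a rose from 4.39 to 33.2 CPM (log2 3.07 ± 0.46), Isg15 from 5.43 to 35.6 CPM and Rtp4 from 7.10 to 44.3 CPM. Gdpd3, a lysophospholipase D, fell from 25.5 to 0.588 CPM (-5.42 ± 0.55), with 3 and 1 UMIs left in the Hmgcs2-KO libraries, so the fitted fold is no bound. Of 9984 genes tested by edgeR, 33 rose and 17 fell, and 703 had an unadjusted p under 0.05 against 499 by chance.

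The other named increases were Mptx2 (log2 2.88 ± 0.24), Irf7, a transcription factor of the interferon response (2.07 ± 0.40), Xaf1 (1.92 ± 0.34), Clps, the colipase (1.87 ± 0.22), and the alpha-defensin family members AY761184 (1.80 ± 0.17), Defa17 (1.58 ± 0.15), Defa-rs1 (1.48 ± 0.14), Defa24 (1.46 ± 0.11) and Defa26 (1.43 ± 0.26). Adjusted p ran from 1.78e-05 for Defa24, which went from 929 to 2557 CPM, to 0.0439 for Irf7. In Hmgcs2-KO, Mptx2 stood at 91.7 CPM in stem-like and 14857 CPM in Paneth-like cells. Clps was among the leading genes of Paneth-like cluster 6. For both, free Paneth RNA cannot be told apart from a rise in the cells themselves, here and in other non-Paneth classes below. The other named decreases were Cfi, a complement protease (-4.20 ± 0.42), the growth factor Fgf1 (-3.99 ± 0.37), Lamtor3, a part of the lysosomal Ragulator complex (-2.42 ± 0.27), S100g, the calcium carrier calbindin (-2.19 ± 0.20), the metallothionein Mt2 (-1.35 ± 0.27), Zg16 (-1.18 ± 0.23), Tcea3 (-0.81 ± 0.15), Car8 (-0.81 ± 0.15) and Gipc2 (-0.75 ± 0.14). Their adjusted p ran from 1.18e-04 for Fgf1 to 0.0464 for Mt2.

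**Figure D3:**
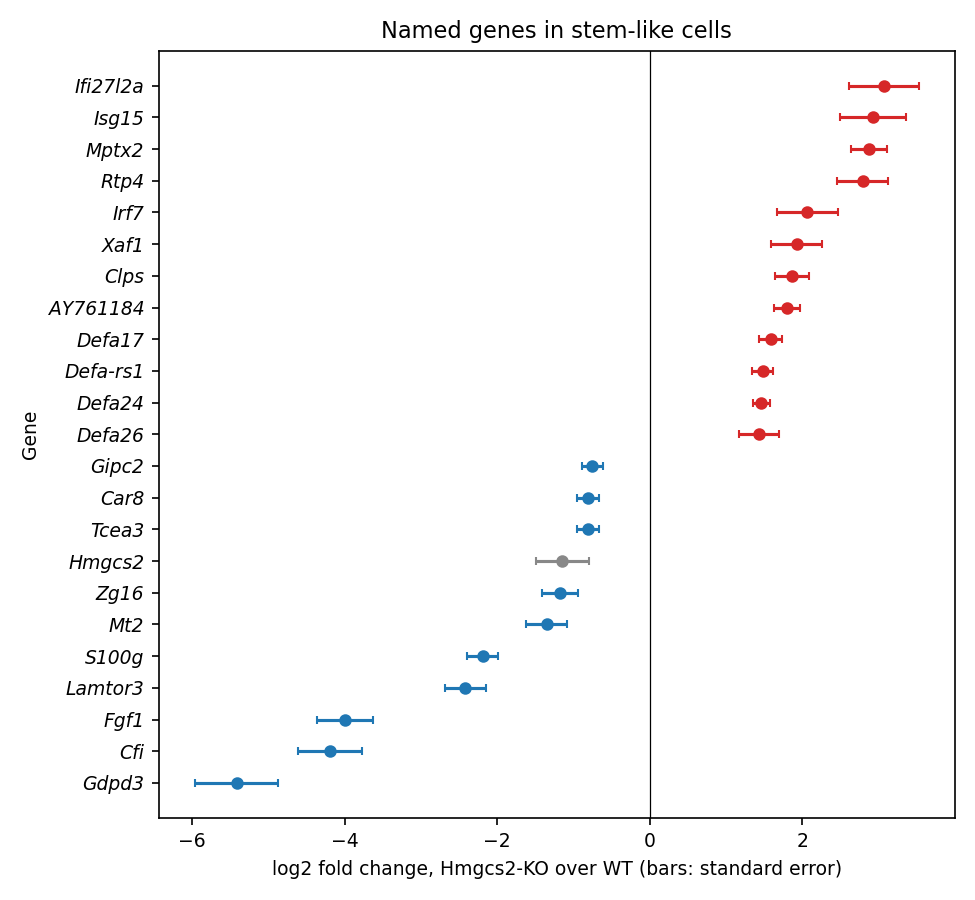
Log2 fold change, Hmgcs2-KO over WT, with standard error for each gene named by the rule in stem-like cells (red, higher; blue, lower; grey, Hmgcs2, which did not pass). Values run from -5.42 for Gdpd3 to 3.07 for Ifi27l2a.

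DESeq2 called 33 genes in stem-like cells, all among the 50 of edgeR, and limma-voom called 42, of which 41 were shared. Leaving out WT replicate 1 gave 32 calls with 21 shared, WT replicate 2 gave 91 with 36 shared, Hmgcs2-KO replicate 1 gave 49 with 36 shared, and the library labelled Hmgcs2-KO replicate 2 gave 99 with 45 shared. Of the genes tested, 489 lie on chromosome 3, the chromosome of Hmgcs2. Of these 4 passed: Cfi (start 129835884), Lamtor3 (137918506) and Gipc2 (152093533) fell, and the alcohol dehydrogenase Adh1 (138260991), named here after its value was seen, rose by 1.15 ± 0.20 log2 units (adjusted p 0.0178).

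**Figure D4:**
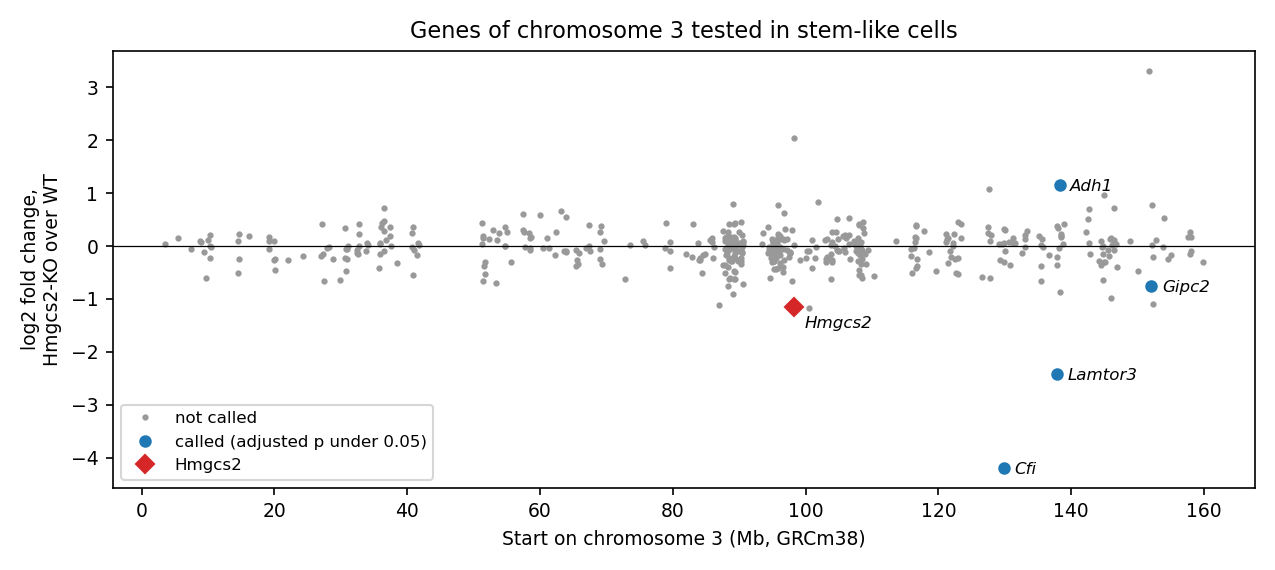
Log2 fold change, Hmgcs2-KO over WT, in stem-like cells for the 489 tested genes of chromosome 3, by start position in Mb (grey, not passing; blue, adjusted p under 0.05; red diamond, Hmgcs2). The 4 passing genes start between 129835884 and 152093533, to the right of Hmgcs2 at 98280435.

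Among lists in stem-like cells, 11 of 25 moved at the preset correlation, and 0 with an estimated correlation and 0 by fry. Paneth cell products rose: of 18 measured, 8 passed over all genes and 13 adjusted over the list alone, with a median of 1.04 (adjusted p 3.79e-23; adjusted p = 0.622 with an estimated correlation). Gm15284 (359 to 1180 CPM), Defa24, Gm14851 (95.4 to 292 CPM) and AY761184 led by p. In the same cells the median share of UMIs from 19 Paneth products was 0.178% and 0.190% in WT and 0.539% and 0.469% in Hmgcs2-KO, and Paneth-like cells were 4.92 times as frequent in Hmgcs2-KO. Interferon response genes rose with a median of 0.84: of 22 measured, Rtp4, Isg15 and Irf7 passed over all genes and 11 adjusted over the list alone (adjusted p 4.63e-13; adjusted p = 0.637 with an estimated correlation). By limma-voom this median was 0.98, and it was 0.30 (adjusted p 0.0114) without WT replicate 1, 1.58 without WT replicate 2 and 1.57 without the library labelled Hmgcs2-KO replicate 2.

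**Figure D5:**
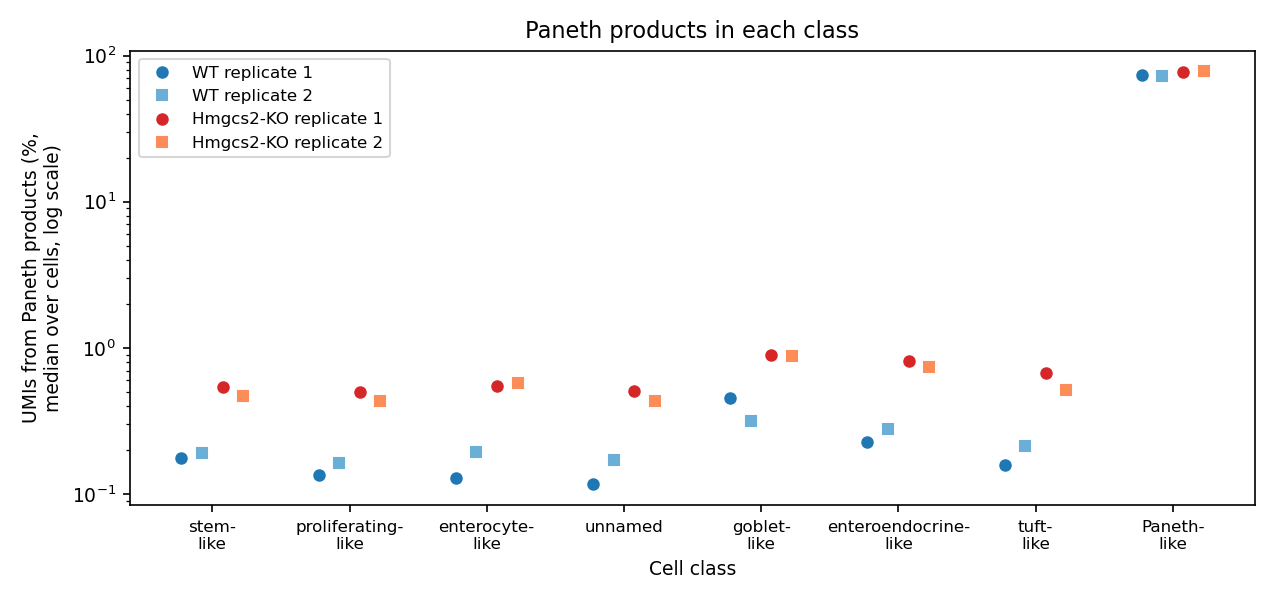
Median share of a cell's UMIs from 19 Paneth products (%, log scale) per cell class, with 1 point per library (blue, WT; red and orange, Hmgcs2-KO). Stem-like cells lie at 0.178% and 0.190% in WT and at 0.539% and 0.469% in Hmgcs2-KO, while Paneth-like cells lie at 72.2% to 77.9%.

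Stem-like cells came from clusters 1 and 26, and cluster 26 held 4.20% of the cells of WT replicate 1 against 0.661%, 1.27% and 1.27% of WT replicate 2 and Hmgcs2-KO replicates 1 and 2, so changes within the class include this mixture. Smaller list changes in stem-like cells were upward for G2 and M phase (median 0.33, adjusted p 1.05e-05; Tubb4b 138 and 170 CPM, Cks2), nuclear oxidative phosphorylation (0.11, 1.94e-04; Cox4i1, Cox8a), endoplasmic reticulum stress (0.24, 9.23e-04; Calr 298 and 375 CPM, Hsp90b1) and antimicrobial and Reg genes (0.07, 0.00334; Itln1 70.4 and 144 CPM, Reg3b, Reg3g). For these the adjusted p = 0.637 with an estimated correlation. Upward changes also met the threshold for cholesterol synthesis (0.13, 0.00865; Fdps 48.0 and 81.8 CPM, Ebp), the citrate cycle (0.14, 0.0255; Mdh2, Suclg1) and S phase (0.10, 0.0220; Slbp, Nasp). Downward changes met it for the stem cell signature (-0.19, 7.07e-05; Slc12a2 570 and 485 CPM, Cdca7) and Wnt targets (-0.21, 0.00196; Ccnd2, Sox9). For these 5 lists the adjusted p = 0.686 with an estimated correlation. Over all genes 1 member, Itln1, passed in these 9 lists. Adjusted over the list alone 4 antimicrobial genes (Itln1, Ang4, Reg4 and Lypd8) and 1 cholesterol gene (Cyp51) were higher and 1 stem gene (Nrn1) was lower. Itln1 and Ang4 are also members of the Paneth product list, and free Paneth RNA was not subtracted.

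Lists that did not pass in stem-like cells included ketone body synthesis and use (median -0.05, adjusted p 0.877; Acat1 108 and 137 CPM, Oxct1 131 and 103), fatty acid oxidation (-0.05, 0.877), the Notch pathway (-0.09, 0.292; Hes1 140 and 152 CPM) and goblet cell products (-0.30, 0.157), where Zg16 alone fell. Fatty acid synthesis (0.08, 0.0754), glycolysis (0.14, 0.169), the mitochondrial genome (0.01, 0.877), secretory progenitors (-0.07, 0.242), enteroendocrine cell products (0.15, 0.877), absorptive enterocyte products (-0.14, 0.552), MHC class II (-0.14, 0.589), dissociation genes (0.07, 0.781), histone deacetylases (0.07, 0.552) and p53 and apoptosis (-0.11, 0.802) did not pass either. Without WT replicate 1, 7 lists moved, and the calls ended for G2 and M phase (adjusted p 0.202), S phase (0.851), the stem cell signature (0.588), Wnt targets (0.828), oxidative phosphorylation (0.260) and endoplasmic reticulum stress (0.113), while the limma-voom medians of the citrate cycle (-0.02) and antimicrobial genes (-0.11) turned and that of cholesterol synthesis went from 0.12 to 0.27. Without WT replicate 2 the limma-voom medians went from -0.18 to -0.33 for the stem cell signature, -0.21 to -0.34 for Wnt targets, 0.11 to 0.21 for oxidative phosphorylation, 0.10 to 0.20 for S phase, 0.15 to 0.24 for the citrate cycle and 0.09 to 0.52 for antimicrobial genes, which stood at 0.44 without Hmgcs2-KO replicate 1, where S phase stood at 0.16. Cholesterol synthesis ended without WT replicate 2 (0.176) and without Hmgcs2-KO replicate 1 (0.345). Wnt targets (0.0567) and endoplasmic reticulum stress (0.0611) also ended without Hmgcs2-KO replicate 1, and the citrate cycle (0.267) and S phase (0.165) without the library labelled Hmgcs2-KO replicate 2.

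In proliferating-like cells much of the same set moved. Ifi27l2a (3.30 to 28.1 CPM, log2 3.14 ± 0.46), Mptx2 (3.12 ± 0.16), Rtp4 (2.80 ± 0.40), Clps (2.13 ± 0.16) and AY761184 (2.02 ± 0.22) rose. Fgf1 (-3.18 ± 0.32), Mt2 (-2.16 ± 0.31), Lamtor3 (-2.15 ± 0.21), S100g (-1.76 ± 0.18) and the brush border enzyme sucrase-isomaltase, Sis (-1.50 ± 0.23), fell. Of 10560 genes, 24 rose and 12 fell by edgeR, and 541 had an unadjusted p under 0.05 against 528 by chance. Interferon response (median 1.13, 1 of 23 over all genes and 14 adjusted over the list alone, adjusted p 1.31e-20) and the stem cell signature (0.11, 0.00324) rose and absorptive enterocyte products fell (-0.32, 5.32e-09), and for these 3 lists the adjusted p = 0.966 with an estimated correlation. Paneth cell products rose too (median 1.58, 8 of 19 over all genes and 14 adjusted over the list alone, 3.29e-38; adjusted p = 0.290 with an estimated correlation). Calls numbered 278 without WT replicate 1, 511 without WT replicate 2, 69 without Hmgcs2-KO replicate 1 and 124 without the library labelled Hmgcs2-KO replicate 2.

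In enterocyte-like cells, whose clusters were mixed in different proportions in each library, the interferon-induced genes Ifit3 (8.42 to 63.1 CPM, log2 2.81 ± 0.29), Ifitm3 (14.9 to 87.4 CPM, 2.57 ± 0.28) and the RNA sensor Dhx58 (1.73 ± 0.20) rose, with Mptx2 (2.56 ± 0.26) and the actin regulator Cap1 (1.39 ± 0.15). Gdpd3 (-3.97 ± 0.40) and the alcohol dehydrogenase Adh6a (552 to 156 CPM, -1.83 ± 0.20) fell. Cluster 4 held 16.8% of the cells of WT replicate 2 and 1.01%, 0.108% and 0.333% of WT replicate 1 and Hmgcs2-KO replicates 1 and 2. Cluster 19 held 7.36% of the library labelled Hmgcs2-KO replicate 2 against 0.594% to 1.13% of the others, and cluster 9 held 6.34% and 6.05% of Hmgcs2-KO against 3.86% and 1.23% of WT, so changes within the class include this mixture. Of 9427 genes, 7 rose and 4 fell by edgeR, whereas DESeq2 called 65 and limma-voom 0, with 572 genes at an unadjusted p under 0.05 against 471 by chance. Interferon response rose with a median of 1.38, with 1 of 27 over all genes and 18 adjusted over the list alone (adjusted p 2.62e-21; adjusted p = 0.750 with an estimated correlation). S phase (0.66, 3.07e-06) and the stem cell signature (0.48, 0.00525) rose and goblet cell products fell (-0.31, 0.00274), also with adjusted p = 0.750 with an estimated correlation. Paneth cell products (1.31, 0 of 19 over all genes and 14 adjusted over the list alone, 1.07e-24), G2 and M phase (1.07, 1.93e-09) and Wnt targets (0.64, 2.57e-04) rose, with adjusted p = 0.643 with an estimated correlation. Calls numbered 426 without WT replicate 1, 133 without WT replicate 2, 0 without Hmgcs2-KO replicate 1 and 3 without the library labelled Hmgcs2-KO replicate 2.

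In Paneth-like cells Mptx2 rose from 5171 to 14857 CPM (log2 1.53 ± 0.26) while its relative Mptx1 fell from 738 to 34.3 CPM (-4.42 ± 0.32, adjusted p 6.65e-06). Tesc (2.29 ± 0.31), Irf7 (1.91 ± 0.23), Ifitm3 (1.68 ± 0.22) and the insulin-degrading enzyme Ide (1.42 ± 0.31) rose. Cfi (-3.93 ± 0.32), S100g (-2.25 ± 0.21), the sialyltransferase St3gal4 (-1.97 ± 0.42) and Cst6 (-1.74 ± 0.35) fell. The class also differed in its make-up: cluster 6 held 9.15% and 9.18% and cluster 18 held 4.06% and 3.78% of Hmgcs2-KO cells, against 0.640% and 1.25% and 1.19% and 2.08% of WT cells. Median UMIs of Paneth-like cells were 7260 and 7553 in WT and 11810 and 10655 in Hmgcs2-KO. Of 7672 genes, 20 rose and 37 fell by edgeR, with depths of 1011847 to 7290468 UMIs per library. Interferon response rose (median 0.99, 3 of 17 over all genes and 8 adjusted over the list alone, adjusted p 1.07e-06). Absorptive enterocyte products fell (-0.94, 1 of 23 over all genes and 10 adjusted over the list alone, 1.64e-12), while 10.5% and 1.59% of Paneth-like cells in WT and 0.784% and 0.332% in Hmgcs2-KO took under 10% of their UMIs from Paneth products. So did MHC class II genes (-0.98, 0 of 7 over all genes and 6 adjusted over the list alone, 7.83e-06). Genes of p53 and apoptosis (0.47, 0.00729), G2 and M phase (0.40, 0.0147) and S phase (0.36, 0.0350) rose and oxidative phosphorylation fell (-0.15, 0.00290). For these 7 lists the adjusted p = 0.647 with an estimated correlation. Calls numbered 363 without WT replicate 1, 96 without WT replicate 2 and 106 without the library labelled Hmgcs2-KO replicate 2.

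In goblet-like cells Ifi27l2a (9.88 to 79.3 CPM, log2 3.05 ± 0.35), Cap1 (1.71 ± 0.16) and Defa-rs1 (1.67 ± 0.21) rose. Mptx1 (1461 to 62.4 CPM, -4.55 ± 0.28), Cfi (-4.37 ± 0.36), Adh6a (-2.75 ± 0.36), Lamtor3 (-2.44 ± 0.20) and Gipc2 (-1.23 ± 0.17) fell. The clusters of the class differed between libraries: cluster 12, with 9 goblet and 9 proliferation markers among its leading genes, held 4.02% and 2.04% of WT and 4.77% and 2.38% of Hmgcs2-KO cells, and cluster 21 held 4.96% of WT replicate 1 against 1.06% to 1.79% of the others. Of 10132 genes, 7 rose and 7 fell by edgeR, and 506 had an unadjusted p under 0.05 against 507 by chance. Interferon response rose (median 0.83, 0 of 24 over all genes and 13 adjusted over the list alone, adjusted p 9.05e-22) and goblet cell products fell (-0.21, 2 adjusted over the list alone, 1.57e-04), while G2 and M phase (0.32, 1.11e-09), Paneth cell products (0.44, 9.86e-05; 2 of 22 higher over all genes, and 10 higher and 4 lower adjusted over the list alone) and oxidative phosphorylation (0.12, 0.00541) rose, and for these 5 lists the adjusted p = 0.824 with an estimated correlation. S phase rose (0.36, 3.93e-06; adjusted p = 0.826 with an estimated correlation) and absorptive enterocyte products fell (-0.31, 0.0132; adjusted p = 0.905 with an estimated correlation). Calls numbered 68 without WT replicate 1, 53 without WT replicate 2 and 72 without the library labelled Hmgcs2-KO replicate 2.

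The last comparison asked whether the genotype effect itself differed between stem-like and enterocyte-like cells. The difference passed for 2 genes by the edgeR interaction test. Ifitm3, which restricts virus entry, had an effect of 0.62 in stem-like and 2.57 in enterocyte-like cells, a difference of -1.95 ± 0.24 (SE) log2 units (adjusted p 0.00136). Ifitm3 was also the leading gene of the stem-like cluster 1, at 4.77 times the mean of the other clusters. In enterocyte-like cells, whose cluster proportions differed between libraries, the stem cell signature (median 0.48), Wnt targets (0.64), S phase (0.66) and G2 and M phase (1.07) stood higher in Hmgcs2-KO as well. Fgf1, named after its values were seen because its mean of 9.0 CPM lies outside the rule, had effects of -3.99 and 0.20 and a difference of -4.10 ± 0.58 (adjusted p 0.00571). That mean is over both classes. Stem-like cells held 27.9 CPM in WT and 1.81 in Hmgcs2-KO, the latter on 6 and 6 UMIs, so the level in enterocyte-like cells was lower. Kcne3 (-1.70 ± 0.31, adjusted p 0.0718), Csrp1 (-3.74 ± 0.69, 0.0729), Ifi27 (1.22 ± 0.23, 0.0803), Ccl20 (2.84 ± 0.56, 0.0996) and Epsti1 (-1.12 ± 0.22, 0.109) missed the threshold. The count was 90 without WT replicate 1, 6 without WT replicate 2, 13 without Hmgcs2-KO replicate 1 and 8 without the library labelled Hmgcs2-KO replicate 2.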

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

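Every test of an explanation below was chosen or given its final form after the result was seen, and the forms that came out otherwise are given with it.

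The genotype effect differed between stem-like and enterocyte-like cells for Fgf1, by -4.10 log2 units, and for Ifitm3, by -1.95 log2 units, each by the edgeR interaction test.

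Paneth-like cells took a larger share of the Hmgcs2-KO libraries. A loss of absorptive cells from the preparation would raise all other classes alike, but the Paneth-like log2 fold change exceeded the mean of 5 other classes by 2.35 (SE 0.656), a form of the test adopted after a ratio to stem-like and proliferating-like cells gave a 2.76-fold difference with widely spread WT libraries. Paneth-like cells of Hmgcs2-KO took a median of at least 77.5% of their UMIs from Paneth products. Clusters were named by many of the same genes, so a raised share was fixed in advance. Only its size argues against other cells with free Paneth RNA being taken for Paneth-like cells. Sampling of another stretch of intestine cannot be told apart, since the proximal and distal lists differed by -0.14 in enterocyte-like cells with members going both ways. Genotype and the crypt yield of the dissociation or sort stay open and untested.

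Paneth transcripts were higher in Hmgcs2-KO in the other classes as well. For stem-like, proliferating-like and enterocyte-like cells free RNA is a candidate explanation. In the Hmgcs2-KO libraries 19 Paneth products kept the proportions of the Paneth-like cells of their library. Correlations across genes were at least 0.938 there, and genes are not independent replicates. That value came only from the third form of the test. With the whole list of 24 genes and enteroendocrine-like cells included the lowest correlation in the Hmgcs2-KO libraries was 0.420. With the 19 genes it was 0.864, at which enteroendocrine-like cells, set apart afterwards, cannot be told apart. Tuft-like cells held at least 4.02 times the level of stem-like cells in both Hmgcs2-KO libraries, which argues against free RNA alone there, and the 10% of tuft-like cells with most of these UMIs held at least 80.1% of them against 27.0% and 21.9% in WT, which may reflect a few droplets that also hold a Paneth cell. A higher Paneth programme in these classes stays open beside both.

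Once the members of the Paneth product and interferon response lists, alpha-defensins and genes named Ifi were left out, which still left interferon-induced genes such as Xaf1 and Oas3, 26 genes differed in at least 2 classes, among them Gdpd3, Cfi, Lamtor3, Mptx1, Cap1 and the pseudogenes Gm10036, Gm5900 and Gm10709, and an effect of Hmgcs2 itself stays open and untested. A strain difference in shared segments cannot be told apart: 17 pairs lay within 20 Mb against a median of 6 in random sets (permutation p 0.0015), but with 1 gene per family of neighbours, a form adopted afterwards, 9 pairs gave a permutation p of 0.0562. A segment carried along with the edited allele could not be settled either. Of the 26 genes 5 lie on chromosome 3 (one-sided Fisher's exact p 0.00796), with the neighbouring relatives Adh1 and Adh6a counted apart. However, 0 lie within 20 Mb of Hmgcs2, the nearest being Cfi at 31.6 Mb. Reg4, which starts at 98222156 beside Hmgcs2, passed in enteroendocrine-like cells alone (-3.19) and stood at 2.05 (adjusted p 0.0691) in stem-like cells. Free Paneth RNA cannot be told apart for the set: 75.0% of the genes with a level in both classes were no more abundant in Paneth-like than in stem-like cells, but Paneth products had been left out beforehand, and Clps, Mptx1 and Mptx2 were still at least 10 times as abundant in Paneth-like cells.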

How the results depend on the processing

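All alternatives were planned before the data were examined, except the removal of the highest doublet scores. In each case below the cause was not tested. Among summary results 195 values under alternatives kept their side and size, 88 moved beyond it, 3 passed the threshold only under the alternative and 1, a gene effect, turned sign. Ratios of shares were sorted by the size of their move alone, and those of stem-like, enterocyte-like, goblet-like and tuft-like cells also turned sign with a library left out. Among single genes and lists 1295 kept their side, 42 passed only under an alternative, 238 passed only in the reported setting and 16 turned sign. The log2 ratio of the Paneth-like share lay between 1.93 and 2.79 under every alternative run. Depth limits the enteroendocrine-like and tuft-like sums, with 105568 to 345726 and 268120 to 1029332 UMIs per library. With no low-count filter the median of all genes moved to 0.13 in Paneth-like and -0.12 in enteroendocrine-like cells.

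Genes called in all cells numbered 2, in stem-like 50, in proliferating-like 36, in enterocyte-like 11, in Paneth-like 57, in goblet-like 14, in enteroendocrine-like 7 and in tuft-like cells 56. DESeq2 called 117 in all cells, 33 in stem-like, 65 in enterocyte-like, 20 in Paneth-like (where 7139 of 7672 genes had no adjusted p), 27 in goblet-like and 28 in tuft-like cells. limma-voom called 0 in all cells, 0 in enterocyte-like, 9 in goblet-like and 4 in enteroendocrine-like cells. Without the low-count filter the counts were 1, 155, 196, 302, 134, 177, 28 and 99 in the order above, 47 for the difference between classes, and Hmgcs2 passed in stem-like cells at -1.14 and in proliferating-like cells at -0.82. Without cell filters 22 were called in enterocyte-like and 7 in goblet-like cells, and with doublets kept 9 in goblet-like cells. With cells thinned to 3000 UMIs the counts were 6 in all cells, 20 in enterocyte-like, 17 in Paneth-like, 3 in enteroendocrine-like and 24 in tuft-like cells. With the highest doublet scores removed, chosen after seeing the data, they were 20 in enterocyte-like, 93 in Paneth-like and 0 in enteroendocrine-like cells. At Leiden resolution 0.5 they were 22 in enterocyte-like and 35 in Paneth-like cells, and at resolution 2.0 they were 31 and 270. With components centred per library they were 17 in enterocyte-like, 36 in Paneth-like, 9 in goblet-like and 2 in enteroendocrine-like cells.

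The replicate block gave 282 calls in all cells, 111 in stem-like, 221 in proliferating-like, 83 in enterocyte-like, 174 in Paneth-like, 3 in enteroendocrine-like and 96 in tuft-like cells, and 1 for the difference between classes when it replaced the library block. Under the block Hmgcs2 passed in stem-like cells at -1.28 (adjusted p 6.91e-05) and in proliferating-like cells at -0.98 (adjusted p 2.82e-05) and stood at 0.0807 in enterocyte-like cells. The replicate numbers are shared between genotypes, and the differences of the 2 replicates correlated across genes at 0.57 in all cells and between 0.02 and 0.18 in the classes, so shared handling of equal numbers cannot be excluded with 2 pairs.

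Leaving out each library in turn gave 2 to 1837 calls in all cells, 32 to 99 in stem-like, 69 to 511 in proliferating-like, 0 to 426 in enterocyte-like, 39 to 363 in Paneth-like, 17 to 72 in goblet-like, 10 to 55 in enteroendocrine-like and 56 to 111 in tuft-like cells, and 6 to 90 for the difference between classes. Lists called ranged from 11 to 16 in all cells and from 7 to 16 in stem-like cells. The log2 ratio of shares ranged from -0.0921 to 1.22 for stem-like, -1.08 to 0.28 for enterocyte-like, 1.93 to 2.79 for Paneth-like, -0.53 to 0.13 for goblet-like, -1.42 to -0.53 for enteroendocrine-like and -0.79 to 1.06 for tuft-like cells. Hmgcs2 in WT stem-like cells against other classes ranged from 2.79 to 3.30. The genotype effect on Hmgcs2 ranged from -1.44 without the library labelled Hmgcs2-KO replicate 2 to 0.32 without Hmgcs2-KO replicate 1 in all cells, from -2.17 to -0.54 in stem-like cells, and in enterocyte-like cells it ranged from -1.51 to 1.81 and turned to 1.81 without WT replicate 1 and to 0.20 without Hmgcs2-KO replicate 1; limma-voom gave 0.65 there.

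No list held with camera's estimated correlation, 0 in all cells and 0 in stem-like cells, or with fry, 0 and 0. Whether the estimated correlation could pass a changed list after adjustment over the lists was not tested. With equal cells per class 16 genes and 6 lists were called in all cells, and the list medians turned for cholesterol synthesis (0.0905), the citrate cycle (7.88e-05), oxidative phosphorylation (0.0147), Wnt targets (-0.0141) and enteroendocrine products (0.32). Leaving out WT replicate 2 turned fatty acid oxidation (5.83e-04), the citrate cycle (0.0155), oxidative phosphorylation (0.0126) and enterocyte products (0.0468), and Hmgcs2-KO replicate 1 turned fatty acid oxidation (0.0204). Over the libraries left out the lowest medians of these 4 lists were -0.493, -0.280, -0.343 and -1.30. In stem-like cells leaving out WT replicate 1 turned the citrate cycle (-0.0236) and antimicrobial genes (-0.112), whose highest medians over the libraries left out were 0.239 and 0.522.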

Other observations

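Enteroendocrine-like cells, 27 to 81 per library, differed in the hormone transcripts summed over the class. They formed cluster 28 alone, whose leading genes included the hormones Gip, Cck and Gcg. A different mix of hormone-making cells cannot be told apart here from a change within the cells. Ghrl, the ghrelin precursor, rose from 4115 to 15240 CPM in Hmgcs2-KO (log2 1.89 ± 0.29, adjusted p 0.0226), and Qpct, the glutaminyl cyclase that matures peptide hormones, rose by 3.40 ± 0.51. Nts, the neurotensin precursor, fell from 886 to 19.5 CPM (-5.25 ± 0.63, adjusted p 0.00797), with 6 and 0 UMIs left, and Reg4 fell from 143 to 15.8 CPM (-3.19 ± 0.53), with 2 and 2 UMIs left, so neither fitted fold is a bound. The Paneth products AY761184 (1.83 ± 0.30) and Defa24 (1.53 ± 0.25) also rose. Of 3019 genes, 5 rose and 2 fell by edgeR, while DESeq2 called 5 higher and 0 lower and limma-voom 4 higher and 0 lower, so Nts and Reg4 passed by edgeR alone among these tools. With the highest doublet scores removed 0 passed by edgeR. In the reported setting 152 genes had an unadjusted p under 0.05 against 151 by chance. Paneth cell products (median 0.81, adjusted p 1.46e-11; 6 higher and 1 lower of 13 adjusted over the list alone; adjusted p = 0.319 with an estimated correlation) rose and secretory progenitor genes fell (-0.48, 2.22e-05; adjusted p = 0.381 with an estimated correlation). Enteroendocrine cell products fell within the class (-0.41, 0.0474; adjusted p = 0.989 with an estimated correlation). Oxidative phosphorylation (0.31, 1.53e-04; adjusted p = 0.932 with an estimated correlation), antimicrobial and Reg genes (1.01, 0.00524; adjusted p = 0.495 with an estimated correlation) and the citrate cycle (0.34, 0.0180; adjusted p = 0.826 with an estimated correlation) rose. Calls numbered 19 without WT replicate 2, 24 without Hmgcs2-KO replicate 1 and 55 without the library labelled Hmgcs2-KO replicate 2.

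Tuft-like cells carried the broadest interferon difference of the classes by count: of 20 measured response genes, 9 rose over all genes and 19 adjusted over the list alone, with a median of 1.52 (adjusted p 8.76e-34; adjusted p = 0.486 with an estimated correlation), and whether this exceeds the other classes was not tested. Clps (4.72 ± 0.33), AY761184 (4.48 ± 0.24) and Mptx2 (4.01 ± 0.46) rose, in cells where a few held most of the Paneth transcripts. Defa23 rose from 0 and 1 UMIs in WT to 13 and 10 in Hmgcs2-KO and Rnase1 from 3 and 0 to 26 and 14 UMIs, where 3 UMIs in WT would be 2.88 and 11 CPM, so their fitted folds are no bounds. Adh6a fell from 42 and 11 UMIs to 2 and 0. Lamtor3 (-2.28 ± 0.37), Adc (-2.48 ± 0.48) and Pla2g12a (-1.36 ± 0.25) fell. Gdpd3 fell too, from 43.2 and 25.6 CPM in WT to 0 UMIs in both Hmgcs2-KO libraries, where 3 UMIs would be 5.45 and 6.53 CPM. Paneth cell products had a median of 3.0 with 11 of 17 over all genes and 14 adjusted over the list alone (1.63e-40; adjusted p = 0.486 with an estimated correlation). Oxidative phosphorylation (0.15, 5.34e-04), antimicrobial and Reg genes (0.62, 9.19e-04), glycolysis (0.35, 0.00657) and G2 and M phase (0.89, 0.00814) rose and secretory progenitor genes fell (-0.35, 0.0225), also with adjusted p = 0.486 with an estimated correlation. MHC class II (0.39, 0.0225) and absorptive enterocyte products (0.16, 0.0468) rose, with adjusted p = 0.696 with an estimated correlation. Of 5739 genes, 48 rose and 8 fell by edgeR. Calls numbered 87 without WT replicate 1 and 111 without WT replicate 2.

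The interferon response list passed at the preset correlation in all cells and in 6 of the 7 classes. With an estimated correlation its adjusted p in these comparisons lay between 0.486 and 0.966, and by fry between 0.256 and 0.984. In enteroendocrine-like cells 3 members were measured and the median was -0.12 (adjusted p 0.999). Barcodes shared between libraries numbered 23 to 33 per pair.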
